A study of Mus musculus with 6 samples.

How the data were processed

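The series measured small RNAs in the complex of retinal pigment epithelium (RPE), choroid and sclera from mouse eyes with laser-induced choroidal neovascularization (CNV), and in the same tissue from eyes without laser. Each of the 6 libraries, 3 control and 3 CNV, came from a pool of 4 eyes per the labels, and groups and replicate numbers were taken from the sample titles. The labels do not say whether the eyes of different pools came from different mice, so the p-values measure the spread between these pools, part of which may be technical. Per the labels' protocols, RNA was extracted with Trizol, small RNA libraries were made from inserts of 14 to 40 nt, and sequencing was run on a NextSeq 500.

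The authors' deposited tables give, for each library, a read count per mature microRNA (miRNA) and per tRNA-derived small RNA (tsRNA). Bowtie is named in the submitters' processing notes, and its version, the genome build, the mismatches allowed and the rule for reads that match several small RNAs are not given in the sources used here. The tables list 1836 miRNAs and 498 tsRNAs, of which 460 are named tRF (tRNA fragments) and 38 tiRNA (tRNA-derived stress-induced RNAs, cut in the anticodon loop). The tsRNA names give the amino acid, the anticodon and a serial number. The sequences behind the serial numbers were not used here.

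The deposited CPM column was not tested, because its values rest on different totals for miRNAs and tsRNAs. For miRNAs the total was the sum of the listed miRNA counts. For tsRNAs it was a larger number than the listed tsRNA counts, 586937 to 1540950 per library, and what it counts is not given in the sources used here. Every listed tsRNA reached at least 20.03 in that column in some library, so the tsRNA list had been restricted to the more abundant ones. A set of 24 miRNAs had counts identical in all 6 libraries to those of another miRNA with a total over 50, among them miR-199a-3p and miR-199b-3p, so their reads were counted for both names.

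Counts were analysed in R 4.3.3. Small RNAs with enough reads were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10 and a minimum total of 15, which left 541 miRNAs and 456 tsRNAs, 997 in all. Both classes were scaled together with trimmed mean of M-values (TMM) factors and fitted in a single model with no covariate. CNV was tested against control with edgeR's quasi-likelihood test, and Benjamini-Hochberg adjustment was run over all 997 with a threshold of 0.05. Levels are CPM, counts relative to the TMM-scaled library total, and standard errors (SE) are on the log2 scale. Log2 values per library used a prior count of 2.

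A set of 13 miRNA lists with 166 members was fixed before the data were examined, covering myeloid and leukocyte, erythrocyte, endothelial and angiogenic, fibroblast and smooth muscle, RPE and pigment cell, photoreceptor, neuron, skeletal muscle and surface epithelium miRNAs, the miR-29 and let-7 families, the miR-17-92 clusters and the Dlk1-Dio3 imprinted cluster. Of these members 159 were tested, each was counted in every control library, and no list shared a member with another. Lists were tested against the other tested miRNAs with camera of limma 3.58.1, two-sided, at a preset correlation of 0.01, and again with the correlation estimated from the data. The fry test, which asks whether a list's members move on balance in a single direction without comparing them with other miRNAs, was run beside it. Groups of tsRNAs by type and by amino acid with at least 5 tested members were tested in the same way among tsRNAs. Shares of counts and mean list levels per library were compared with two-sided exact permutation tests of the difference of group means, for which 3 against 3 cannot give a p under 0.1.

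The rule for the small RNAs named in the text was also fixed before the data were examined. It used CPM with total counts as the only scaling. It took the called miRNAs and tsRNAs with a mean of at least 10 CPM whose CNV values all lay on the same side of all control values, up to 10 miRNAs and 5 tsRNAs in each direction. In a class with fewer than 3 of these, it added the 3 with the smallest p. It added the 5 most abundant miRNAs, the 3 most abundant tsRNAs and the 3 members of each list with the smallest p. Other members of the lists, and miRNAs outside the rule, are named in places and were chosen after their values were seen. Positions of miRNA genes are from the GENCODE M21 annotation of mouse build GRCm38, matched by name for miRNAs with a single annotated gene.

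The libraries held 5057140 to 12839400 counts, and control replicate 2 was the deepest. The whole test was checked on simulated counts for the same 997 small RNAs, drawn independently of each other. In each of 10 draws 200 picked at random were changed, and the tested members of the neuron list were lowered 2-fold as well. The test recovered 68.3% of 2-fold and 99.3% of 4-fold changes, with 4.13% of its calls false. With so many changed, the adjusted threshold is easier to pass than in the real data, where 3 small RNAs were called. These recovery shares therefore do not hold for the real data, where fewer changes of these sizes may be found. With no change simulated it made a median of 0 calls and at most 2. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom was at least 82.7 for each pair. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, each class analysed alone, a minimum fold of 1.5, the replicate number as a block, and each library left out in turn. Added after the data were seen were identical miRNAs kept once, control replicate 2 thinned to the mean depth of the others, total-count scaling for the lists and groups, and tsRNA groups by anticodon.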

Results

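Small RNAs were sequenced from RPE-choroid-sclera complexes, the layers behind the neural retina from which new vessels grow in CNV. The eyes came from male mice of 7 to 8 weeks. In the CNV group each eye received 25 laser spots (532 nm, 100 mW, 0.1 s, 50 µm), which rupture the membrane under the RPE, and tissue was taken 7 days later. Control eyes were from age-matched mice without laser. Each group had 3 libraries, each from a pool of 4 eyes. The control libraries held 5225590, 12839400 and 5057140 counts and the CNV libraries 5820320, 5321440 and 5656810. Between 1159 and 1666 miRNAs were detected per library, with the most in control replicate 2, which was also the deepest. Values are mean ± SD over the 3 pools of a group (n = 3) unless stated otherwise.

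The first comparison asked which miRNAs differ between CNV and control tissue. The miRNA miR-21a-5p, which is induced in many tissues by injury and inflammation, rose 3.54-fold, from 12615 ± 3812 to 44686 ± 6145 CPM (log2 fold change 1.82, SE 0.23). Both arms of the miR-10a precursor, whose gene lies in the Hoxb cluster, rose as well. The main arm miR-10a-5p went from 245 ± 59.1 to 696 ± 150 CPM, a 2.84-fold change (log2 1.51, SE 0.23), and the rare arm miR-10a-3p from 1.75 ± 0.209 to 8.08 ± 1.97 CPM, a 4.69-fold change (log2 2.23, SE 0.29). The level of miR-10a-3p rested on 9 to 21 counts per control library and 36 to 52 per CNV library. All 3 CNV pools lay above all 3 control pools for each of these miRNAs. Their adjusted p was 0.0183 for miR-21a-5p, 0.0183 for miR-10a-3p and 0.0452 for miR-10a-5p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No other miRNA of the 541 tested passed, and none fell. The closely related miR-10b-5p, which could share reads with miR-10a-5p, was at 737 ± 119 and 901 ± 53.6 CPM (log2 0.29).

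In build GRCm38 the miR-21a gene lies on chromosome 11 at 86584067 to 86584158 on the minus strand, within an exon of the annotated Vmp1 gene. The miR-10a gene lies on the same chromosome at 96317165 to 96317274 on the plus strand, outside any annotated host gene. The most abundant miRNAs were miR-99a-5p, miR-1a-3p, miR-143-3p, miR-26a-5p and miR-27b-3p, with log2 fold changes of -0.08, 0.12, 0.29, 0.15 and 0.07, none past the threshold. At an unadjusted p under 0.05 there were 95 miRNAs, 46 higher and 49 lower, where 27.1 would be expected by chance. Related miRNAs can vary together, so how far such a count strays by chance was not tested. In CPM with total counts as the only scaling, the groups did not overlap for 134 miRNAs (24.8%, against 10% by chance). Of these, 44 were higher and 90 lower in CNV. With that scaling the median log2 fold change of the miRNAs was -0.14, against 0.01 under TMM, so lower values were favoured. DESeq2 called 22 miRNAs, 16 higher and 6 lower, and limma-voom called only miR-21a-5p, miR-10a-5p and miR-10a-3p. The simulated counts were tested with edgeR only, so the false calls of DESeq2 were not checked. Leaving out control replicate 2, control replicate 3, CNV replicate 1 or CNV replicate 2 left 0 calls. Leaving out CNV replicate 3 gave 17, 10 higher and 7 lower. Without a filter on low counts 50 miRNAs were called, 18 higher and 32 lower, and with a minimum mean of 20 CPM none was.

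**Figure D1:**
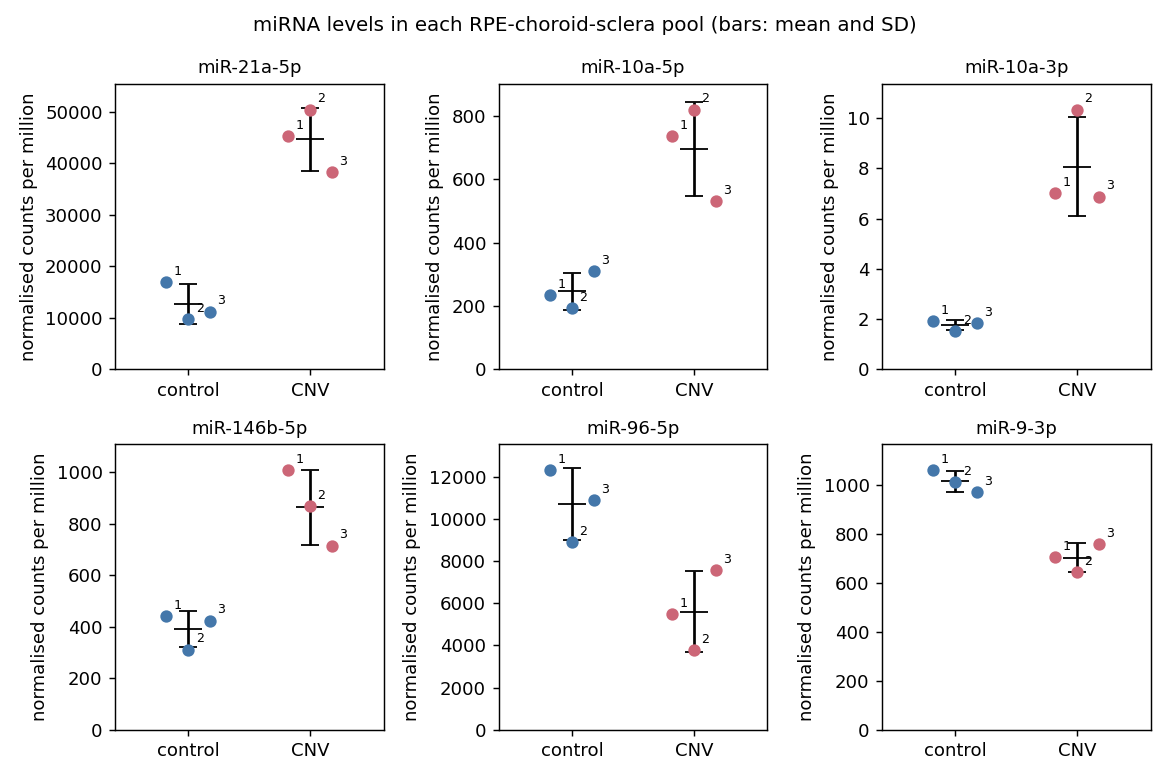
Levels (TMM-normalised CPM) of 6 miRNAs in each pool, with control in blue, CNV in red, replicate numbers beside the points and bars for mean and SD (n = 3). For miR-21a-5p the CNV pools lie between 38230 and 50464 and the control pools between 9742 and 16940, and the CNV pools lie above the controls for the first 4 miRNAs and below them for miR-96-5p and miR-9-3p.

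The myeloid and leukocyte miRNAs, made by the white blood cells that enter inflamed tissue or induced in inflammation, rose as a group by camera at its preset correlation. The adjusted p of the list was 4.6e-06 in that test, 0.345 with an estimated correlation and 0.0598 with fry. Of the 12 tested, 11 had a positive fold change, with a median log2 fold change of 0.69 under TMM and 0.54 with total counts as the only scaling. Over all small RNAs 1 member passed edgeR's test, miR-21a-5p, and adjusted over the list alone 6 rose and 1 fell. DESeq2 over all small RNAs also called miR-146b-5p, miR-142a-3p, miR-142a-5p and miR-223-3p higher (adjusted p 0.000399, 0.00946, 0.0137 and 0.0116). Among these, miR-146b-5p, a target of inflammatory signalling, was 2.20-fold higher (392 ± 70.7 to 864 ± 147 CPM, log2 1.14). The blood cell miRNAs miR-142a-3p (40.4 ± 7.02 to 72.5 ± 2.98 CPM), miR-142a-5p (210 ± 35.0 to 442 ± 132 CPM) and the myeloid miR-223-3p (77.9 ± 2.04 to 123 ± 10.5 CPM) were 1.79-fold, 2.11-fold and 1.58-fold higher. The member that fell adjusted over the list alone was miR-150-5p, typical of mature lymphocytes (213 ± 26.4 to 152 ± 16.9 CPM, log2 -0.48). The mean level of the list was 0.78, 0.75 and 0.45 log2 units above the control mean in CNV replicates 1 to 3. In the same libraries the mean level of the photoreceptor list was -0.95, -1.32 and -0.35 and that of the neuron list -0.62, -1.19 and -0.54.

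Photoreceptor and neuron miRNAs fell as groups by camera at its preset correlation, with an adjusted p of 7.3e-04 and 4.6e-06. Both lists were at an adjusted p of 0.345 with an estimated correlation, and at 0.153 and 0.110 with fry. All 5 tested members of the photoreceptor list, from the miR-183, miR-96 and miR-182 cluster that is abundant in photoreceptors, were lower in CNV under each scaling, with a median log2 fold change of -0.92. None passed edgeR's test over all small RNAs, where DESeq2 called miR-96-5p lower (adjusted p 0.0332), and adjusted over the list alone 4 fell. The level of miR-182-5p was 31500 ± 7442 CPM in control and 16657 ± 7267 CPM in CNV, that of miR-183-5p 24080 ± 5670 and 13930 ± 3488, and that of miR-96-5p 10709 ± 1719 and 5615 ± 1920. All 11 tested neuron miRNAs were lower under each scaling, with a median of -0.83, and 6 fell adjusted over the list alone. None passed edgeR's test over all small RNAs, where DESeq2 called miR-138-5p and miR-9-3p lower (adjusted p 0.0298 and 0.0220). Among the 6, the brain and retina miRNA miR-124-3p was at 5943 ± 2123 and 2769 ± 1319 CPM (log2 -1.10), miR-9-3p at 1015 ± 44.1 and 704 ± 57.8 (log2 -0.53), miR-138-5p at 25.8 ± 7.40 and 13.1 ± 1.80 (log2 -0.97) and miR-137-3p at 5.37 ± 1.36 and 2.24 ± 0.776 (log2 -1.21). By library, the neuron levels of all CNV pools lay below all control pools (exact permutation p = 0.1, adjusted over 13 lists 0.26), while the photoreceptor level of CNV replicate 3 (-0.35) lay above that of control replicate 2 (-0.40; exact permutation p = 0.2, adjusted 0.371).

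The RPE and pigment cell list, built on miR-204 and miR-211, fell in the same test at an adjusted p of 0.0296, against an adjusted p of 0.345 with an estimated correlation and 0.129 with fry. Of its 5 members 4 were lower under each scaling, and the median was -0.39. The miR-211 gene lies in an intron of Trpm1 on chromosome 7 (64205806 to 64205911) and the miR-204 gene in an intron of Trpm3 on chromosome 19 (22750605 to 22750672). Adjusted over the list alone 1 member fell, miR-211-3p, from 24.4 ± 2.72 to 12.9 ± 2.04 CPM (log2 -0.91). Over all small RNAs none passed edgeR's test, and DESeq2 called miR-211-3p lower (adjusted p 0.0116). The main arm miR-211-5p was at 1862 ± 63.8 CPM in control and 1423 ± 176 in CNV (log2 -0.39), and miR-204-3p at 45.0 ± 11.6 and 31.8 ± 4.89 (log2 -0.50). The exception was miR-184-3p, also abundant in cornea and lens, at 10841 ± 2160 and 16585 ± 7487 CPM (log2 0.61, not past the test). The camera call ended without control replicate 3 (0.0502), CNV replicate 2 (0.0829) or CNV replicate 3 (0.0609). By library, the mean level of the list was -0.06, -0.60 and -0.30 log2 units from the control mean in CNV replicates 1 to 3. In control replicates 1 to 3 it was -0.04, -0.03 and 0.07 (exact permutation p = 0.1, adjusted over 13 lists 0.26).

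**Figure D2:**
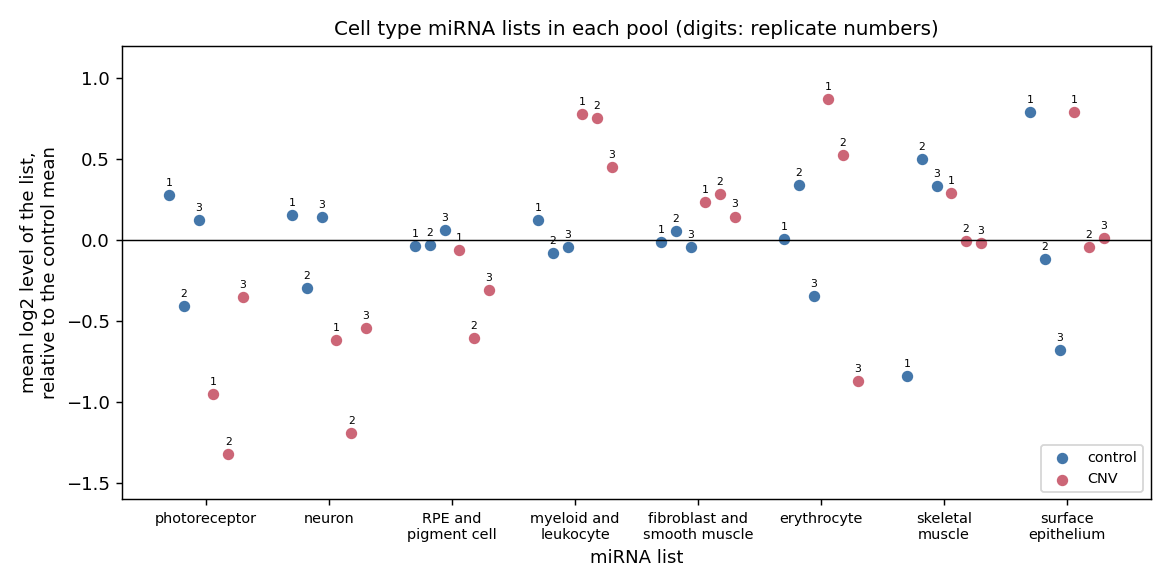
Mean log2 level of 8 miRNA lists in each pool relative to the mean of the 3 control pools, with control in blue, CNV in red and replicate numbers above the points. The neuron list lies between -0.54 and -1.19 in the CNV pools and the myeloid and leukocyte list between 0.45 and 0.78, while the erythrocyte list runs from -0.87 to 0.87 within the CNV group.

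Fibroblast and smooth muscle miRNAs rose as a group by camera at its preset correlation, at an adjusted p of 0.0284, against an adjusted p of 0.345 with an estimated correlation and 0.0598 with fry. The median log2 fold change was 0.30 under TMM and 0.16 with total counts as the only scaling, and the mean of 0.22 was 0.07 with total counts and 0.14 without CNV replicate 2. Of 10 members 9 were positive under TMM, 7 with relative log expression factors and 6 with total counts as the only scaling. The scar-associated miR-214-3p, which lies in an exon of the noncoding gene Dnm3os on chromosome 1 (162223368 to 162223477), was the only member that rose adjusted over the list alone, from 673 ± 50.1 to 1036 ± 129 CPM (log2 0.62). Over all small RNAs none passed edgeR's test, and DESeq2 called miR-214-3p higher (adjusted p 0.0294). Its cluster partner miR-199a-5p was at 10300 ± 871 CPM in control and 14888 ± 2309 in CNV (log2 0.53), and miR-199a-3p, which shares its reads with miR-199b-3p, at 33934 ± 1586 and 42332 ± 1193 (log2 0.32). The miR-29 family list, which holds 5p as well as 3p arms, fell as a group in the same test at an adjusted p of 0.0456. It was at an adjusted p of 0.345 with an estimated correlation and 0.122 with fry. Of its 6 members 5 were lower, with a median of -0.30 under TMM and -0.45 with total counts as the only scaling, where all 6 were. No member passed adjusted over the list alone. The largest difference was that of miR-29c-3p, at 175 ± 27.3 and 128 ± 13.1 CPM (log2 -0.45), and the most abundant member miR-29a-3p was at 8261 ± 1565 and 8591 ± 1494 (log2 0.06, and -0.11 with total counts as the only scaling). Both calls ended without control replicate 3 (0.0792 and 0.0520), CNV replicate 2 (0.0645 for each) or CNV replicate 3 (0.0609 and 0.101), that of the miR-29 family also without control replicate 1 (0.0973). The fibroblast and smooth muscle call also ended with total counts as the only scaling (0.0545), and both ended with identical miRNAs kept once (0.0568 for each).

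The let-7 family, which is abundant in differentiated tissue, was called upward by camera at its preset correlation, at an adjusted p of 0.0017, against an adjusted p of 0.472 with an estimated correlation and 0.171 with fry. By library the groups overlapped, since the level of control replicate 3 (0.20) lay above that of CNV replicate 3 (0.13; exact permutation p = 0.2, adjusted over 13 lists 0.371). All 9 tested members were positive under each scaling, with a median log2 fold change of 0.33 under TMM and 0.18 with total counts as the only scaling. Without control replicate 2 the mean log2 fold change of the family was 0.17 rather than 0.36 (camera adjusted p 0.0459). Adjusted over the list alone let-7i-5p rose, from 16423 ± 2618 to 28286 ± 5964 CPM (log2 0.78). The other members had log2 fold changes of at least 0.18, with let-7e-5p at 0.41 and miR-98-5p at 0.39. Over all small RNAs none of the family passed edgeR's test, and DESeq2 called let-7i-5p higher (adjusted p 0.0377). These miRNAs differ from each other by few bases, so their reads may be shared.

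Endothelial and angiogenic miRNAs did not differ as a group. The endothelial miR-126a-3p was at 38356 ± 5122 CPM in control and 36176 ± 3933 in CNV (log2 -0.08). The hypoxia-induced miR-210-3p was at 511 ± 72.4 and 339 ± 87.5 (log2 -0.59), miR-212-5p at 22.7 ± 2.20 and 31.9 ± 3.38 (log2 0.50) and miR-23b-3p at 4540 ± 254 and 5641 ± 776 (log2 0.31). None of the 13 members passed, also not adjusted over the list alone, and the camera adjusted p was 0.859. The mean of the voom fold changes was positive (0.00097) and camera's direction was down, since camera compares with the other miRNAs.

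No call was made for the remaining lists. The erythrocyte list had a camera adjusted p of 0.829, with miR-451a at 1461, 1259 and 599 CPM in the control pools and 2935, 2302 and 449 in the CNV pools, and miR-486a-5p, whose counts equal those of miR-486b-5p, at 704 ± 117 and 866 ± 349 CPM. The skeletal muscle list had an adjusted p of 0.859, with log2 fold changes of -0.80 for miR-499-5p, 0.27 for miR-133b-3p and 0.22 for miR-206-3p, and 355.5 CPM of miR-206-3p in control replicate 1 against 1721 to 2812 in the other pools. The surface epithelium list had an adjusted p of 0.318, with log2 fold changes of 0.42 for miR-203-3p, 0.52 for miR-205-5p and -0.60 for miR-141-3p. The miR-17-92 list had an adjusted p of 0.580, with -0.49 for miR-20b-5p, 0.62 for miR-18a-5p and 0.35 for miR-106b-3p. The Dlk1-Dio3 cluster, with 52 members tested, had an adjusted p of 0.343, with 0.95 for miR-494-3p, 0.49 for miR-329-3p and 0.41 for miR-299a-3p. None of the members of these 5 lists passed edgeR's test adjusted over the list alone, and DESeq2 over all small RNAs called miR-494-3p higher (adjusted p 0.0161). With fry their adjusted p was 0.923, 0.923, 0.820, 0.820 and 0.527. Leaving out CNV replicate 3 brought the erythrocyte list to an adjusted p of 0.0153, and leaving out control replicate 1 brought the surface epithelium list to 4.77e-04, both upward.

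**Figure D3:**
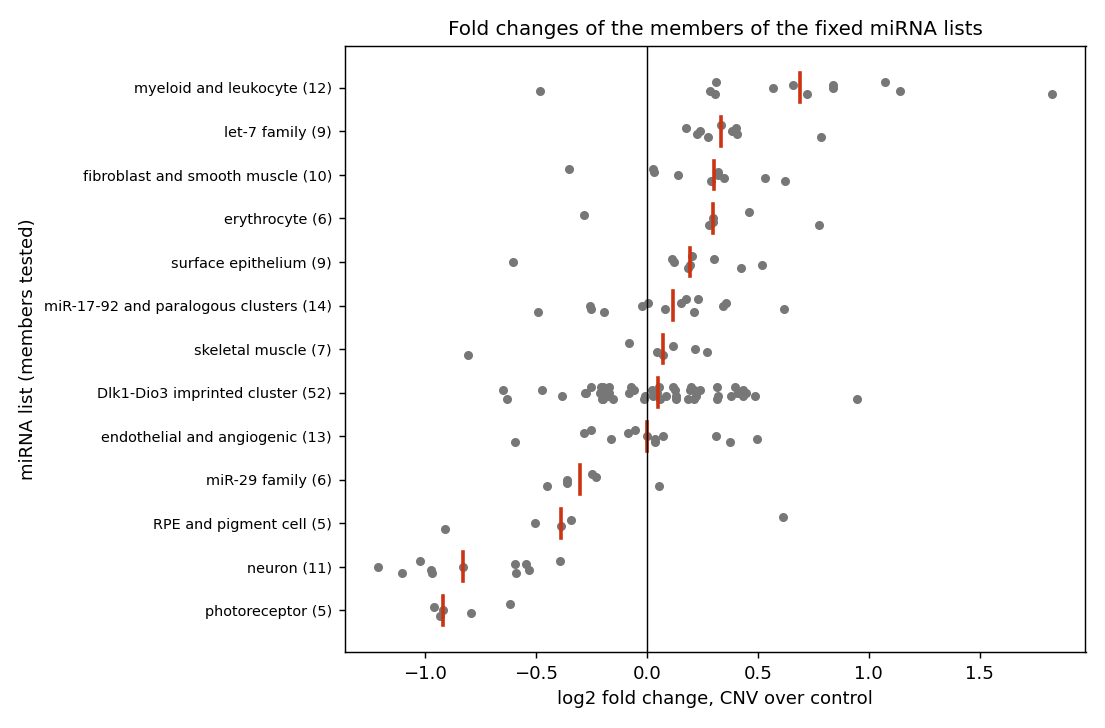
Log2 fold change of CNV over control for each tested member of the 13 miRNA lists (grey points) with the median of each list (red line). The medians run from -0.92 for the photoreceptor list to 0.69 for the myeloid and leukocyte list, and that of the endothelial and angiogenic list lies at 0.00011.

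The second comparison asked which tsRNAs differ. No tsRNA of the 456 tested passed, and the smallest adjusted p was 0.127 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 82, of which 62 were higher and 20 lower, where 22.8 would be expected by chance. Fragments of the same tRNA can vary together, with an estimated correlation of 0.16 for Gly-CCC and 0.48 for Gly-GCC. How far such a count strays by chance was not tested. DESeq2 called 16, 11 higher and 5 lower, and limma-voom 0. The most abundant tsRNAs were named as fragments of the glycine tRNA with anticodon CCC. The sequences behind the names were not used, so reads shared with other glycine tRNAs cannot be excluded. The level of tRF-Gly-CCC-026 was 21471 ± 3632 CPM in control and 41859 ± 12357 in CNV (log2 0.96, SE 0.24), that of tRF-Gly-CCC-027 5594 ± 1199 and 11695 ± 4906 (log2 1.06, SE 0.33), and that of tRF-Gly-CCC-025 3929 ± 1823 and 12992 ± 4844 (log2 1.73, SE 0.38). The smallest p values were those of tRF-Gly-CCC-025, tRF-Glu-CTC-016 and tRF-Arg-ACG-012, which did not pass. The rare tRF-Glu-CTC-016 was at 9.31 ± 1.28 and 2.72 ± 1.82 CPM (log2 -1.74, SE 0.39) and tRF-Arg-ACG-012 at 58.9 ± 0.778 and 98.9 ± 14.8 (log2 0.75, SE 0.17). In CPM with total counts as the only scaling, the groups did not overlap for 67 tsRNAs (14.7%, against 10% by chance). Of these, 29 were higher and 38 lower in CNV. With that scaling the median log2 fold change of the tsRNAs was -0.07, against 0.08 under TMM, so lower values were favoured. Without CNV replicate 3 there were 7 calls, 4 higher and 3 lower, among them the 3 abundant Gly-CCC fragments, and without control replicate 1 there was 1, tRF-Gly-GCC-015. Without a filter on low counts 38 were called, 27 higher and 11 lower.

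The share of counts taken by tsRNAs was 5.45 ± 0.902% in control and 8.63 ± 2.07% in CNV, a difference of 3.17 percentage points (exact permutation p = 0.2, adjusted over 3 shares 0.2). The CNV pools ran from 6.47% in replicate 3 to 10.6% in replicate 2, and the control pools from 4.78% to 6.48%. Without tRF-Gly-CCC-026 the difference was 1.61 points. Within the tsRNAs, the tiRNA share was 6.60 ± 1.11% in control and 4.40 ± 0.110% in CNV, and the share of Gly-CCC fragments 65.0 ± 3.65% and 75.1 ± 3.50%. For each of these the groups did not overlap (exact permutation p = 0.1, the smallest possible, adjusted 0.15). As a share of all counts, tiRNAs were at 0.356 ± 0.0532% in control and 0.380 ± 0.0971% in CNV (exact permutation p = 0.9, not adjusted).

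**Figure D4:**
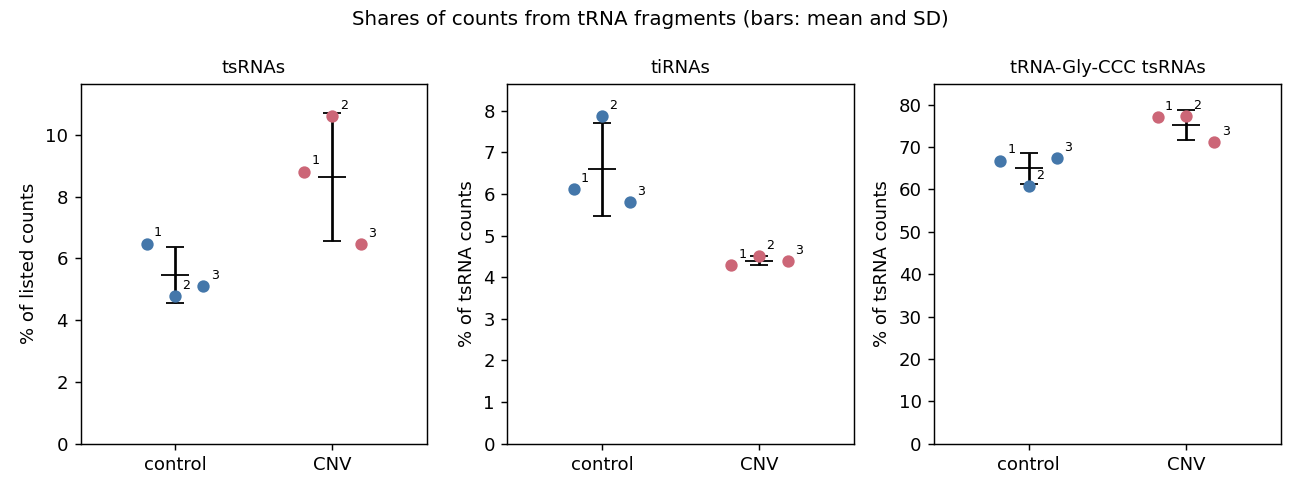
Percent of listed counts from tsRNAs, and percent of tsRNA counts from tiRNAs and from Gly-CCC fragments, in each pool, with control in blue, CNV in red, replicate numbers beside the points and bars for mean and SD (n = 3). The tsRNA share overlaps between the groups, with 6.48% in control replicate 1 and 6.47% in CNV replicate 3, and the Gly-CCC share does not, with at most 67.3% in control and at least 71.1% in CNV.

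Of the 22 tsRNA groups by type and amino acid, only the cysteine tRNA fragments were called by camera at its preset correlation, downward at an adjusted p of 0.0443, against an adjusted p of 0.780 with an estimated correlation and 0.517 with fry. All 9 tested were negative under each scaling, with a median log2 fold change of -0.30, although none passed adjusted over the group alone. The camera adjusted p was 0.0729 with total counts as the only scaling, 0.122 with no filter on low counts, 0.0672, 0.382 and 0.186 without control replicates 1, 2 and 3, and 0.0797 and 0.124 without CNV replicates 1 and 2, so the call ended in each case. The mean log2 fold change of -0.33 was -0.09 without control replicate 2 and -0.20 without control replicate 1. The proline and lysine fragments had an adjusted p of 0.0507 each, downward, and the glycine fragments 0.143, upward. The tRF type and the tiRNA type both had 0.234. The median log2 fold change of the tRFs was 0.07, and -0.08 with total counts as the only scaling, and camera's direction for them was down relative to the tiRNAs, whose median was 0.37. The histidine, isoleucine and serine fragments also had positive medians and a downward camera direction, at adjusted p of 0.574, 0.621 and 0.579. The other groups had adjusted p of at least 0.158. Without CNV replicate 3, 5 groups were called, among them the glycine fragments (0.0145), and without control replicate 1 the glycine (0.0366) and proline (0.00346) fragments were. The lysine fragments were called without control replicate 3 (0.00209), and the lysine and proline fragments with no filter on low counts (0.0353 each).

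A grouping by anticodon was added after the data were seen, and among 39 anticodons it called Gly-CCC upward and Cys-GCA downward, with adjusted p of 0.0053 and 0.0393 by camera. Both were at an adjusted p of 0.948 with an estimated correlation, and fry gave 0.473 and 0.545. Of 33 Gly-CCC fragments tested, 27 were positive under TMM and 25 with total counts as the only scaling, and 12 rose adjusted over the group alone, which is not independent evidence, since the group was chosen on these libraries. The Gly-GCC fragments had 13 of 19 positive, and none passed adjusted over the group alone. Both groups rest on the names, so reads shared between Gly-CCC and Gly-GCC fragments cannot be excluded.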

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

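Chosen only after the data were seen were identical miRNAs kept once, thinning of control replicate 2, total-count scaling for lists and tsRNA groups, and anticodon groups. The count of called miRNAs, 3, was 2 with relative log expression factors (miR-10a-5p at an adjusted p of 0.0571 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 3 in 5 settings (total counts, a 1.5-fold minimum, limma-voom, identical miRNAs once and thinning), 22 with DESeq2, 50 with no filter, 6 with each class alone and 0 at a mean of 20 CPM or more, which tests 321 miRNAs. The same 3 were among the calls with DESeq2, with no filter and with each class alone. With each replicate left out the count ran from 0 to 17. The tsRNA count, 0, was 16 with DESeq2, 38 with no filter, and 0 to 7 with each replicate left out. Of the 13 lists 7 were called, 0 with an estimated correlation, 4 to 7 with each replicate left out, and 5 to 7 in the other settings. Among the camera settings, calls of the myeloid, photoreceptor, neuron and let-7 lists ended only with an estimated correlation. That correlation was 0.25, 0.93, 0.42 and 0.82 for these lists, while the other settings kept the preset of 0.01. The fry test made none of these calls, with adjusted p of 0.0598, 0.153, 0.110 and 0.171. In simulated data a 2-fold shift of the neuron list was called in 10 of 10 draws with the preset correlation. It was called in 0 with an estimated correlation, so that test can miss such a shift. The simulated members were drawn independently, unlike the real list with its estimated correlation of 0.42. The draws therefore do not show that the call with the preset correlation is sound. Of the tsRNA groups 1 was called, 0 with an estimated correlation, 2 with no filter, 0 with total counts, 2 by anticodon and 0 to 5 with each replicate left out. The tsRNA share difference ran from 2.19 to 4.25 points with each replicate left out. Whether the replicate numbers pair the pools is not settled. Deviations of same-numbered pools correlated at 0.29, 0.03 and 0.17, and each CNV pool correlated best with its same-numbered control. The margin was narrow for CNV replicate 2 (0.01 with control replicate 1) and CNV replicate 3 (0.15 with control replicate 2). Control replicate 2 correlated best with CNV replicate 3. With the replicate block 23 miRNAs (11 higher, 12 lower), 13 tsRNAs, 6 lists and 1 tsRNA group were called. The 6 lists held 5 of the 7: the RPE and miR-29 calls ended (0.0822 each) and surface epithelium was gained (0.0429), and the tsRNA call moved from cysteine (0.0581) to proline (0.0288). For the named small RNAs, 744 values across settings stayed on their side of the threshold, 48 passed only in the alternative and 16 no longer passed. For lists and groups the numbers were 354, 13 and 31, and no called value changed sign. The adjusted p of miR-21a-5p reached at most 0.236, that of miR-10a-3p 0.236 and that of miR-10a-5p 0.310, with log2 fold changes of 1.57 to 2.10, 1.96 to 2.32 and 1.26 to 1.66. Total-count scaling moved the median log2 fold change of all small RNAs by -0.16. Apart from construction (fewer pools or small RNAs tested), the cause was not tested.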

Other observations

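The tests of neural retina RNA, of a shift by abundant small RNAs and of the label and retina content of CNV replicate 3 were chosen only after the result was seen, as were the miR-34 family and the Gly-CCC fragments as groups. The miR-34 family, which is induced by p53 and, for miR-34b and miR-34c, abundant in ciliated cells, had higher values in CNV. All 5 tested members had log2 fold changes of 0.92 to 1.12 under TMM and of 0.77 to 0.97 with total counts as the only scaling. The level of miR-34c-5p was 184 ± 10.9 CPM in control and 373 ± 61.1 in CNV, that of miR-34a-5p 119 ± 5.70 and 228 ± 55.5, and that of miR-34b-5p 42.2 ± 6.04 and 91.9 ± 19.5 (n = 3). All CNV pools lay above all control pools for these 3. Adjusted over the family alone 5 passed, which is not independent evidence, and none did over all small RNAs, where miR-34c-5p had an adjusted p of 0.0568 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 over all small RNAs called miR-34c-5p, miR-34b-5p, miR-34a-5p and miR-34b-3p higher (adjusted p 0.000103, 0.00135, 0.0106 and 0.0306), and with each class alone edgeR called miR-34b-5p and miR-34c-5p. The miR-34a gene lies on chromosome 4 (150068454 to 150068555), and those of miR-34b (51103562 to 51103645) and miR-34c (51103034 to 51103110) lie together on chromosome 9 in GRCm38.

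The total behind the deposited tsRNA per-million values exceeded the listed tsRNA counts in each library. Listed tsRNAs made up 44.7 ± 5.26% of it in control and 58.6 ± 5.38% in CNV (n = 3, exact permutation p = 0.1, the smallest possible).

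With 3 pools against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3 miRNA calls, the highest other split 2, and 1 of the 10 splits gave as many as the real one. For tsRNAs the real split gave 0 calls, so 10 of the 10 splits gave as many, and the highest other gave 3. That split set control replicate 1 with CNV replicates 1 and 2 against control replicates 2 and 3 with CNV replicate 3, and it also gave the 2 miRNA calls. It follows no batch named in the labels.

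Photoreceptor and neuron miRNAs were lower together in the CNV pools by camera at its preset correlation, though both lists were at an adjusted p of 0.345 with an estimated correlation. A push downward by abundant small RNAs that rose is argued against, because with total counts as the only scaling the other miRNAs had a median log2 fold change of -0.118 against -1.01 for the members of both lists. The greater depth of control replicate 2 is argued against as well, since without that library the median of the members was -1.17 rather than -0.87. Whether the CNV pools held less neural retina RNA stays open. The means of the lists differed by -0.048 (SE 0.105 over members), but that both lay below 0 was known before the test, and the photoreceptor members come from a single cluster, so their agreement adds little. Retina left at dissection and retinal cells lost to the laser, which the design would also allow, were not tested apart.

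The log2 levels of CNV replicate 3 correlated at 0.988 with control replicates 2 and 3, at 0.983 with control replicate 1 and at 0.982 and 0.984 with CNV replicates 1 and 2. The myeloid and leukocyte miRNAs go against a control pool under a CNV label. The mean level of the 11 other than miR-21a-5p in CNV replicate 3 lay 0.250 log2 units above the highest control (control SD 0.0795). The called miR-21a-5p was left out, since its call already rested on this pool. Its other arm miR-21a-3p was kept, as were miR-146b-5p, miR-142a-3p and miR-223-3p. For the last 3, all CNV pools were already known to lie above all controls. Leaving out miR-21a-5p alone therefore does not make this check independent. The list was chosen after its levels were seen, so a wrong label is not excluded. This pool also lay below all controls in the neuron list (-0.54, lowest control -0.30). In the photoreceptor (-0.35) and let-7 (0.13) lists it lay within the control range. CNV replicate 3 may hold more retina than the other CNV pools. On a scale from 0 at the control mean to 1 at the mean of the other CNV pools it stood at 0.31 for photoreceptor, 0.60 for neuron and 0.59 for myeloid miRNAs, so its mean retinal position minus the myeloid position was -0.133, short of the difference of 0.2 set for the test. More retina and a milder response to the laser in this pool cannot be told apart from these values.

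The mean level of the 33 Gly-CCC fragments differed by 0.47 log2 units (SE 0.15) between CNV and control, with 6 members negative. None passed edgeR's test over all small RNAs, where DESeq2 called 5 higher, and 21 did not pass over the group alone. The call by camera (adjusted p 0.0053) was lost with an estimated correlation (adjusted p = 0.948) and not made by fry (0.473). More red cell RNA in the CNV pools is argued against as the whole cause. With the red cell miRNA miR-451a as a covariate the difference was 0.409 (SE 0.119). Other parts of blood are not covered by this covariate and were not tested. Whether cleavage of tRNA or another source of fragments differs between the groups stays open and was not tested.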
